A study of Mus musculus with 2 samples.

How the data were processed

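Mammary luminal cells sorted from Sox9-GFP mice (group WT) and from Sox9-GFP;C3-TAg mice (group C3-TAg) were profiled with a Chromium 3′ single-cell kit, 1 library per group. The deposited files hold UMI counts per gene and barcode for 31053 genes, made by the authors with Cell Ranger 3.1.0 on mm10, per the submitters' processing notes and the file headers. The counts are whole numbers that were not normalized. How the barcodes were called is not given in the sources used here, and the lowest totals per barcode were 502 UMIs in WT and 500 in C3-TAg. The transcripts of the reporter and of the T antigen have no row of their own and were not measured. Groups were taken from the labels. No cell annotation was used.

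All values were computed from the deposited counts with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and scikit-learn 1.9.0. Barcodes with fewer than 500 genes, fewer than 1000 UMIs or over 10% of UMIs from mitochondrially encoded genes were left out, which kept 7406 of 8993 WT and 8458 of 9575 C3-TAg barcodes. Doublets were called with Scrublet in each library and removed, 360 in WT (4.86%) and 588 in C3-TAg (6.95%). Kept cells had medians of 10296 and 8672 UMIs and of 2795 and 2773 genes. Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were ranked within each library, and 30 principal components with 15 nearest neighbours entered Leiden clustering at resolution 0.5. Clusters were then put into compartments by the mean log2 ratio of marker lists, cluster against all other cells, with 5 CPM added to each level. A cluster was stromal or immune where a list of non-epithelial markers had a mean over 1 that was not under that of the hormone-sensing luminal markers, receptor-expressing where the latter had a mean over 1, and otherwise receptor-negative. This rule was chosen after the data were seen, whereas the marker lists, gene lists, thresholds and alternatives were fixed before the data were examined. The named classes failed the check that no cluster has more markers of another class among its leading genes, so clusters were compared by number.

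Counts were summed per library and compartment and divided by the total, giving levels in CPM. Levels carry exact Poisson intervals, ratios of C3-TAg over WT exact conditional Poisson intervals, and shares exact Clopper-Pearson binomial intervals, all at 95%. Where a share was 0, the share that 3 counts of the total would give is printed as its limit. These intervals cover counting error only, since cells of 1 library are not replicates, and no p-value was computed. A library with no UMI of a gene was set to a floor of 3 counts per library, and such a ratio is a lower bound. List medians hold such genes at their bound. Total depth behind the comparisons was 51573936 UMIs in WT and 63550533 in C3-TAg receptor-negative cells, and 26351022 and 13392927 in receptor-expressing cells. Before shares of cells with a UMI were compared, each cell was thinned to 2000 UMIs and shallower cells were left out.

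Gene lists were the immune checkpoint ligands, MHC class I and class II presentation, interferon response, NF-kB and cytokines, secretory and antimicrobial genes, E2F and S phase, G2M, CDK inhibitors and Rb family, p53 targets, milk proteins and lipid secretion, hormone sensing, basal keratins and contractile genes, luminal differentiation, fetal mammary and neural crest, mesenchymal, cartilage matrix SOX9 targets, Notch pathway, Wnt pathway, hypoxia and glycolysis, NRF2 targets, squamous, dissociation and immediate early genes, mitochondrially encoded genes and a sex check. A member was measured with at least 20 UMIs over both libraries and counted as higher or lower from a ratio of 1.5. Aldoa was not measured because its symbol names 2 rows. Each list median was set beside 10000 random lists of the same size matched on mean expression in 20 bins, and its interval is the order-statistic interval over members. The text names, per comparison, the 12 genes with the highest and the 12 with the lowest ratio among genes with at least 50 CPM in a library, leaving out mitochondrially encoded, ribosomal, immunoglobulin and unnamed genes. It also names Sox9 and Vtcn1, and from each list up to 2 members at either end among those with at least 20 CPM. Of the genes this rule picks, the text describes a part, and 2 were left out on request. For cells with a Sox9 UMI it names the 10 genes with the highest smaller ratio of both libraries among those with at least 50 CPM.

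The ratio step was tested on simulated Poisson counts drawn from the pooled means at the real depths, with 200 genes changed. These counts hold no spread between cells or animals, so the simulation checks the computation under counting error only. For the receptor-negative comparison it ran on 2842 genes. The direction was right for 100.0% of genes changed by 1.5-fold and by 4-fold, the intervals held the true value for 92.0% of each, and 0% of the unchanged genes passed 1.5-fold. For the receptor-expressing comparison, on 2828 genes, the intervals held the true value for 95.0% and 91.0%. The alternatives were a mitochondrial maximum of 20%, a minimum of 1000 genes, called doublets kept, Leiden resolutions of 0.3 and 1.0, clustering without the 1091 genes that differed 2-fold or more between the libraries, and each library clustered on its own. Others were TMM scaling (edgeR 4.0.16 in R 4.3.3), CPM without milk and mitochondrially encoded genes, means of per-cell CPM, cycling cells left out, list members with at least 100 UMIs or any UMI, thinning to 5000 UMIs or none, and at least 3 G2M UMIs. Leaving out epithelial clusters of under 100 cells was added after seeing the data. Coordinates of Sox9 and Vtcn1 come from the GENCODE annotation of GRCm38, the assembly also called mm10. Figures were drawn with matplotlib 3.10.9.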

Results

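Luminal epithelial cells were sorted by flow cytometry from the mammary glands of FVB/NJ mice at 3.5 months of age and profiled by droplet-based single-cell RNA sequencing. The WT library came from mice with a Sox9-GFP reporter, and the C3-TAg library from mice that carried the same reporter together with the C3-TAg transgene, which drives the simian virus T antigens in mammary epithelium. T antigen binds and inactivates the p53 and Rb tumour suppressors, and the model develops mammary tumours. Each genotype was represented by 1 library, so no difference has a replicate check and no test across samples was possible. The intervals of levels, ratios and shares are 95% intervals that cover counting error only. Those of list medians describe the spread over list members and cover somewhat less than 95%. The WT matrix held 8993 barcodes with 91133082 unique molecular identifiers (UMIs), a median of 9670 per barcode, and the C3-TAg matrix held 9575 barcodes with 91932121 UMIs, a median of 8397. The study submitted 10000 cells per sample. After filtering and removal of called doublets, 7046 WT cells and 7870 C3-TAg cells were kept.

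The kept cells formed 14 clusters, and in 12 of them at least 95% of the cells came from a single library. A cluster that comes almost wholly from 1 library may reflect that library and not a cell type. Clusters 5, 6 and 7 carried the hormone receptor genes, with Pgr, the progesterone receptor, at 132.6, 124.0 and 115.1 CPM and Esr1, the estrogen receptor, at 58.8, 97.4 and 80.5 CPM. In clusters 1 and 3, which had most cells of each library outside this group, Csn2, the milk protein beta-casein, was at 11277 and 28844 CPM. Some leading genes of a cluster were markers of another class (Dcn in clusters 6 and 7, Krt14 in cluster 1, Krt17 in cluster 2), so clusters were compared by number and not as named cell types. Clusters 5, 6 and 7 are called receptor-expressing and clusters 1, 2, 3, 4, 8, 9, 10, 11 and 14 receptor-negative. Cluster 14, of 10 WT cells, missed the receptor-expressing rule with a mean of 0.903 although it had 79.1 CPM of Esr1 and 96.1 CPM of Pgr. It also had 5555 CPM of Csn2 and 141.3 CPM of Elf5, and its median of 19481 UMIs was the highest of all clusters. Doublets that were not called are not excluded for it. Clusters 12 and 13 had endothelial and myeloid genes and stayed outside the comparisons. Cluster 12 also had basal genes, with a mean of 3.49 for the basal markers and 1466 CPM of Krt14. The group called stromal or immune may thus hold basal cells.

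Receptor-expressing clusters held 38.7% of kept WT cells (2726 of 7046, exact binomial interval 37.5 to 39.8%) and 21.7% of kept C3-TAg cells (1706 of 7870, 20.8 to 22.6%). Receptor-negative clusters held 60.7% of WT cells (59.5 to 61.8%) and 78.1% of C3-TAg cells (77.2 to 79.0%). Stromal or immune clusters held 0.624% of WT cells (44 cells, 0.454 to 0.837%) and 0.191% of C3-TAg cells (15 cells, 0.107 to 0.314%). Clustering without the 1091 genes that differed between the libraries placed 99.8% of cells in the same compartment, and clustering each library on its own 97.4%. The latter put 0.979% of WT and 4.65% of C3-TAg cells into stromal or immune clusters, which turned the direction of that difference, and 73.7% of C3-TAg cells into receptor-negative ones. The gate of the sort is not described in the sources used here and can set these shares.

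**Figure D1:**
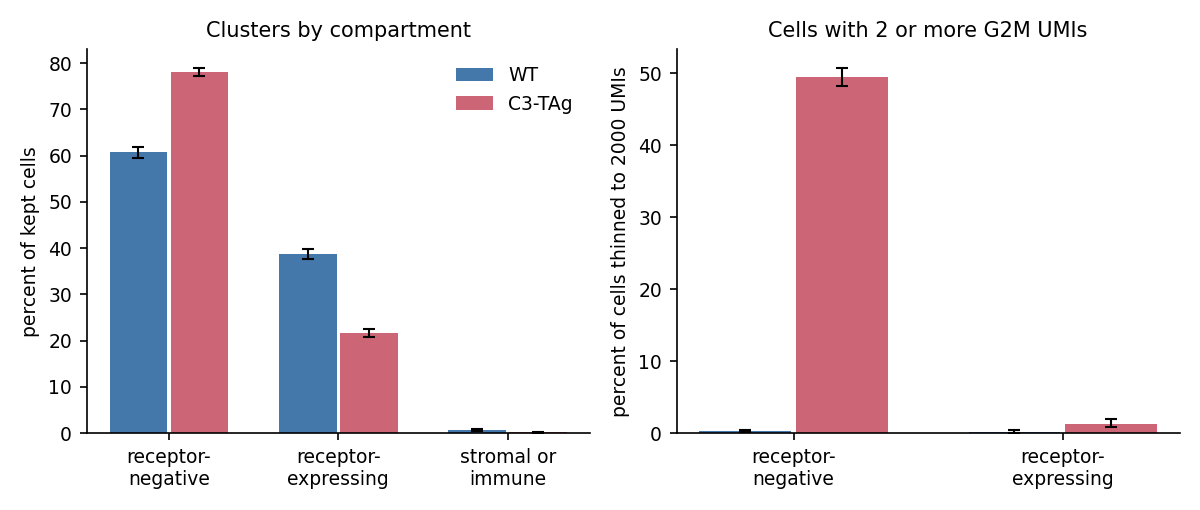
Left, percent of kept cells in receptor-negative, receptor-expressing, and stromal or immune clusters of each library (bars) with exact 95% binomial intervals (whiskers). Right, percent of cells thinned to 2000 UMIs that held at least 2 UMIs over 20 genes of the G2 and M phases; the receptor-negative bars stand at 0.235% in WT and 49.5% in C3-TAg.

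The study title names an axis between SOX9 and B7x. Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760, plus strand, GRCm38) encodes a transcription factor of progenitor cells. Vtcn1 (ENSMUSG00000051076, chromosome 3, 100825459 to 100896922, plus strand) encodes B7x, a surface ligand that restrains T cells. In the receptor-negative clusters both genes were slightly lower in C3-TAg by CPM and about 1.5-fold lower with TMM scaling. The log2 ratio of Vtcn1 there was -0.03 once cells with 2 or more G2M UMIs were left out. Without thinning, 79.1% of C3-TAg and 2.20% of WT receptor-negative cells held that many, so this step falls mostly on C3-TAg. Sox9 was at 472.1 CPM in WT and 430.5 CPM in C3-TAg, a log2 ratio of -0.13 (-0.16 to -0.11). Vtcn1 was at 16.1 CPM in WT and 13.9 CPM in C3-TAg, a log2 ratio of -0.21 (-0.35 to -0.07). In the receptor-expressing clusters Vtcn1 was 4.46-fold lower in C3-TAg (3.65 to 5.51), at 7.91 CPM against 35.3 CPM, and Sox9 was 1.38-fold lower (1.34 to 1.42), at 428.4 against 590.2 CPM. Vtcn1 was at 27.7 CPM (25.0 to 30.6) in WT cluster 6 and 44.4 CPM (40.7 to 48.3) in WT cluster 7. Both lay above the 7.99 CPM of C3-TAg cluster 5, but the size of the fold depends on the mix of the WT clusters. Across all kept epithelial cells the log2 ratio was -0.25 for Sox9 and -0.81 for Vtcn1. With trimmed-mean (TMM) scaling these 2 values became -0.56 and -1.12, those in the receptor-negative clusters -0.58 and -0.65, and those in the receptor-expressing clusters -0.56 and -2.25.

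Within the C3-TAg library the 2 genes differed between receptor-negative clusters. Sox9 was at 305.6 CPM in cluster 1 and 326.2 CPM in cluster 8, and at 583.5 CPM in cluster 2 and 583.3 CPM in cluster 9. Vtcn1 was at 9.52 CPM in cluster 1 (8.40 to 10.7) and 8.77 CPM in cluster 8, and at 19.3 CPM in cluster 2 (17.6 to 21.2) and 23.6 CPM in cluster 9. The WT receptor-negative clusters 3 and 4 lay at 454.5 and 455.2 CPM of Sox9 and at 16.9 and 15.6 CPM of Vtcn1. Cluster 10 of the WT library had 655.7 CPM of Sox9 and 12.8 CPM of Vtcn1.

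**Figure D2:**
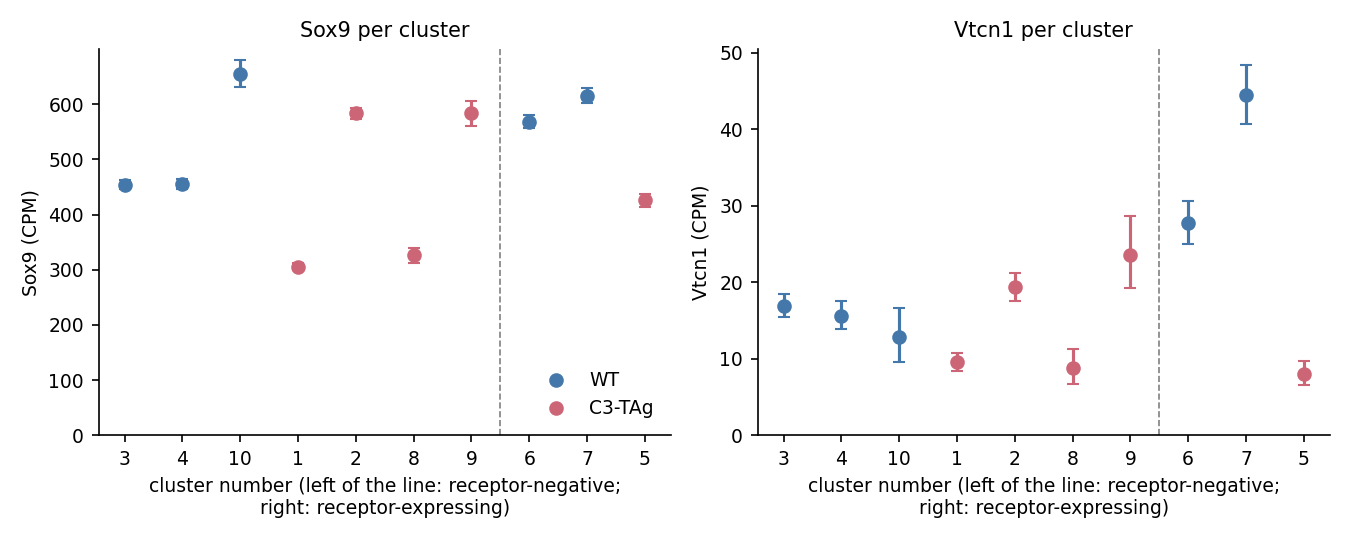
Sox9 (left) and Vtcn1 (right) in CPM for each epithelial cluster with at least 100 cells of a library, coloured by library, with exact 95% Poisson intervals that cover counting error only. In the C3-TAg library both genes were higher in clusters 2 and 9 than in clusters 1 and 8, and Vtcn1 was at 7.91 CPM in the C3-TAg receptor-expressing cells against 35.3 CPM in the WT ones.

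In cells thinned to 2000 UMIs, a Sox9 UMI was found in 53% of WT receptor-negative cells (51.5 to 54.5%) and 49.8% of C3-TAg ones (48.6 to 51.1%), and in 57.3% (55.4 to 59.2%) and 43.1% (40.8 to 45.5%) of receptor-expressing cells. Of the stromal or immune cells, 18.2% of 44 WT cells and 21.4% of 14 C3-TAg cells held one. A Vtcn1 UMI was found in 3.26% of WT and 2.63% of C3-TAg receptor-negative cells. In receptor-expressing cells the shares were 7.32% (6.37 to 8.37%) and 1.23% (0.764 to 1.88%). At 2000 UMIs, 0 of 44 WT stromal or immune cells held a Vtcn1 UMI, which allows a share of up to 6.82%, and without thinning 1 of 44 did. Without thinning, the shares with a Vtcn1 UMI were 16.9% and 12.4% in receptor-negative cells and 25.9% and 5.63% in receptor-expressing cells, at median depths of 11423, 9322, 9382 and 7590 UMIs. The unthinned shares with a Sox9 UMI were 89.5% and 86.3%, and 86.2% and 73.7%. Median depth in the stromal or immune cells was 5526 UMIs in WT and 8616 in C3-TAg. Thinning left out 17 and 26 receptor-negative cells and 8 and 2 receptor-expressing cells of WT and C3-TAg.

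Vtcn1 was then compared between cells with and without a Sox9 UMI, thinned to 2000 UMIs and pooled over the clusters of each compartment. In C3-TAg receptor-negative cells Vtcn1 was at 15.9 CPM in the 3052 cells with a Sox9 UMI and 11.4 CPM in the 3071 cells without, a log2 ratio of 0.48 (0.02 to 0.94). In WT receptor-negative cells the log2 ratio was -0.09 (-0.59 to 0.41). It was 0.07 (-0.34 to 0.49) in WT and 0.26 (-1.13 to 1.64) in C3-TAg receptor-expressing cells, where C3-TAg had 21 cells with a Vtcn1 UMI. At 5000 UMIs both of these turned, to -0.32 (-0.63 to -0.001) in WT, an interval that excluded 0, and to -0.44 (-1.22 to 0.37) in C3-TAg. The C3-TAg receptor-negative value was 0.29 (-0.04 to 0.63) at 5000 UMIs per cell and 0.14 (-0.28 to 0.57) with called doublets kept, and both of these intervals included 0. In C3-TAg at 2000 UMIs, a Sox9 UMI was found in 40.1% of cluster 1 cells and 59.4% of cluster 2 cells. Vtcn1 was at 9.52 and 19.3 CPM in these clusters without thinning. The pooled C3-TAg receptor-negative ratio can thus reflect the mix of clusters, and no ratio was computed within a cluster. The genes with the highest ratios in cells with a Sox9 UMI, in both libraries of the receptor-negative clusters were Klf4, Ptn, S100a6, Crip1, Hspb1, Cxcl2, Lgals3, Notch1, Tsc22d4 and S100a16. Klf4, a transcription factor of epithelial barrier and stem cells, had log2 ratios of 0.55 in WT (0.31 to 0.79) and 0.76 in C3-TAg (0.65 to 0.86), and S100a6 had 0.48 and 0.54. In the receptor-expressing clusters they were Krt6a, Rdh10, Il18r1, Aqp3, Ets1, Specc1l, Pfkfb3, Cebpb, Slco2a1 and Trp53inp1. Krt6a, a keratin of activated epithelium, had log2 ratios of 0.58 in WT (0.18 to 0.98) and 0.84 in C3-TAg (0.38 to 1.31). The ratios of all these genes also pool the clusters of a compartment, so the mix of clusters is not excluded for them. They were picked as the highest of 2230 receptor-negative and 2559 receptor-expressing genes ranked, and their intervals do not allow for that choice. The C3-TAg interval of Il18r1 included 0 (-0.018 to 0.884).

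In the receptor-negative clusters the C3-TAg library carried a large set of cell cycle transcripts that were close to absent in WT. All 20 G2M genes were at least 1.5-fold higher in C3-TAg, with a median log2 ratio of 6.70 (order-statistic interval 6.45 to 7.38), and so were all 23 genes of the E2F and S phase list, with a median of 4.72 (3.74 to 5.66). Both medians lay above all of 10000 random lists matched on expression. Mki67, the proliferation antigen, was at 1.05 CPM in WT and 173.8 CPM in C3-TAg. Ccna2, the cyclin of S and G2 phase, was at 0.0969 and 69.6 CPM. Pclaf, a clamp-associated factor of DNA replication, was at 1.73 and 323.9 CPM. Cenpe, Kif11, Kif4, Anln, Diaph3 and Esco2, genes of chromosome segregation, cytokinesis and cohesion, had log2 ratios between 7.15 and 8.81. At 2000 UMIs per cell, 0.235% of WT receptor-negative cells (0.113 to 0.431%) and 49.5% of C3-TAg ones (48.3 to 50.8%) held at least 2 G2M UMIs. In receptor-expressing cells the shares were 0.221% (0.081 to 0.480%) and 1.29% (0.811 to 1.95%). Unthinned, they were 2.20% and 79.1% in receptor-negative cells and 1.83% and 6.45% in receptor-expressing cells. Whether free RNA from receptor-negative cells adds to the receptor-expressing shares was not tested. Among stromal or immune cells at 2000 UMIs, 0 of 44 WT cells, which allows up to 6.82%, and 2 of 14 C3-TAg cells did, and without thinning 2 of 44 and 4 of 15.

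Of 14 measured genes of CDK inhibitors, D cyclins and the Rb family, 9 were at least 1.5-fold higher and 2 lower in the C3-TAg receptor-negative clusters, with a median log2 ratio of 1.49 (0.41 to 2.5). Cdkn2a, which encodes the tumour suppressors of the INK4A and ARF reading frames, had no UMI in WT and 71.0 CPM in C3-TAg, at least 1220-fold higher against a floor of 3 counts. Cdkn2c, another INK4 inhibitor, was 5.67-fold higher. Rb1 and Ccnd1 were the lower members, at 42.2 against 110.4 CPM and at 33.7 against 78.1 CPM. Of 21 p53 target genes, 9 were higher, 3 lower and 9 within 1.5-fold, with a median of 0.38, or -0.07 with TMM scaling. Pmaip1 and Plk2 were 19.9-fold and 7.51-fold higher, and Trp53inp1 and Ccng1 were 3.73-fold and 1.89-fold lower. Ankrd1, a target of the Hippo pathway, was at 0.233 CPM in WT and 83.9 CPM in C3-TAg. Fn1, the matrix protein fibronectin, had 1 UMI in WT and 58.6 CPM in C3-TAg, with a log2 ratio of 11.56 (9.08 to 16.87). Over all cells of a cluster, Fn1 was at 121.1, 38.7 and 991.8 CPM in clusters 2, 9 and 11. It was at 1.38 CPM in cluster 1 and 0.552 CPM in cluster 8, so its rise was not shared by all C3-TAg receptor-negative clusters.

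Milk genes were lower in the C3-TAg receptor-negative clusters. Of 16 measured genes for milk proteins and lipid secretion, 12 were at least 1.5-fold lower and 2 higher, with a median log2 ratio of -1.58 (-2.40 to -0.74), below all random lists. The list took 8.77% of WT and 1.83% of C3-TAg UMIs in these clusters. Spp1, the secreted phosphoprotein osteopontin, was at 23766 CPM in WT and 1479 CPM in C3-TAg, a log2 ratio of -4.01. Btn1a1, a butyrophilin of the milk fat globule, was 9.95-fold lower, while Glycam1, a mucin-like milk protein, was 4.90-fold higher and Fabp3, a fatty acid binding protein, was at 31.7 and 31.8 CPM. Of 12 secretory and antimicrobial genes, 8 were lower and 1 higher, with a median of -1.10 (-1.94 to -0.55). Tspan8, a tetraspanin, and Lcn2, an iron-binding antimicrobial protein, were 15.6-fold and 4.68-fold lower. Wfdc2 was 1.95-fold higher, but with called doublets kept its log2 ratio turned to -0.12. Hey1, a Notch target, was at 100.1 CPM in WT and 1.57 CPM in C3-TAg, and Cck, the peptide hormone cholecystokinin, at 432.1 and 9.17 CPM. Clic6, Arhgef6, Ceacam10, Cbr2, Fcgbp, Hp, Ggt5 and Itgb3 were the remaining lowest genes, with log2 ratios between -5.46 and -3.52. TMM scaling moved the zero point of the log2 ratios by 0.44 in the receptor-negative clusters, by 0.31 over all epithelial cells and by 0.09 in the receptor-expressing clusters, and ratios are to be read against that shift.

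The basal keratins Krt14 and Krt17 were higher in the C3-TAg receptor-negative clusters. Of 16 genes for basal keratins and contractile proteins, 9 were higher and 4 lower, with a median log2 ratio of 1.06 (-0.20 to 3.70). Krt17 was at 18.7 CPM in WT and 255.4 CPM in C3-TAg, and Krt14 was at 33.4 and 436.9 CPM and Krt5 at 4.17 and 0.598 CPM (the last 2 chosen after their values were seen). Krt17 was at 20.3 CPM in cluster 1 and 618.1 CPM in cluster 2, and Krt14 at 457.1 and 378.4 CPM, so cluster 1 was close to WT for Krt17 only. Without thinning, a Krt5 UMI was found in 11 of 4276 WT cells (0.257%) and 17 of 6149 C3-TAg cells (0.276%), and 4 of the 11 lay among the 10 WT cells of cluster 2. Tpm2, a tropomyosin, was 23.9-fold higher. At 2000 UMIs, 4.51% of WT receptor-negative cells (3.91 to 5.18%) and 49.0% of C3-TAg ones (47.7 to 50.2%) held a UMI of Krt5, Krt14 or Krt17. Krt14 alone was found in 3.59% and 39.9%, and Krt5, the basal keratin partner of Krt14, in 0.141% and 0.065%. The 3-keratin share was 0.662% and 3.05% in receptor-expressing cells, 20.5% of 44 WT and 21.4% of 14 C3-TAg stromal or immune cells, and 2.78% and 48.6% of called doublets in WT and C3-TAg. Without thinning it was 14.2% and 74.9% in receptor-negative and 2.46% and 10.8% in receptor-expressing cells. Krt14 was at 12.3 CPM in C3-TAg receptor-expressing cells against 436.9 CPM in receptor-negative ones, so free RNA is not excluded for the receptor-expressing share. Acta2, Myh11 or Tagln, contractile genes of myoepithelium, were found in 2.0% and 4.52% of receptor-negative cells (6.17% and 9.27% unthinned), 0.846% and 0.293% of receptor-expressing cells (2.97% and 1.82% unthinned), and 20.5% and 28.6% of stromal or immune cells. The stromal or immune shares of keratin and contractile genes include cluster 12, which carried basal genes. They are therefore not a background free of basal cells. A hormone receptor gene (Esr1, Pgr or Prlr) together with Elf5 or Kit was found in 5.94% of WT and 3.94% of C3-TAg receptor-negative cells, against 22.5% and 10.1% of called doublets, 4.55% of WT and 0 of 14 C3-TAg stromal or immune cells, and 0.846% and 0.704% of receptor-expressing cells. Without thinning, these shares were 44.9% and 30.3% in receptor-negative and 3.6% and 1.93% in receptor-expressing cells. Most receptor UMIs of the receptor-negative cells were Prlr, with 4013 in WT and 3472 in C3-TAg. Esr1 had 137 and 143 UMIs there and Pgr 58 and 83, so these shares mainly describe Prlr.

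Genes of luminal differentiation split, with 7 of 17 higher and 2 lower, a median log2 ratio of -0.19 and a mean of 0.22, but 2 higher and 9 lower with TMM scaling (median -0.63). Krt7 was 4.68-fold higher, and Krt19 and the alveolar transcription factor Elf5 were 2.25-fold and 1.91-fold lower. Among 10 measured genes of fetal mammary and neural crest cells, 5 were higher and 0 lower, with a median of 0.55 (-0.34 to 1.87). With TMM scaling 4 were higher and 4 lower, with a median of 0.11. The highest median of this list under an alternative was 1.20. Sox11, a transcription factor of embryonic progenitors, was at 0.175 CPM in WT and 34.6 CPM in C3-TAg, while Sox10 and Sox4 were 1.33-fold and 1.26-fold lower. Over all cells of a cluster, Sox11 was at 79.0, 33.7 and 212.6 CPM in clusters 2, 9 and 11, against 1.45 and 1.66 CPM in clusters 1 and 8. Of 14 mesenchymal genes, 6 were higher and 7 lower, with a median of -0.31 and a mean of 0.87. Under the alternatives the mesenchymal median ran from -0.76 to 0.54, so its sign was not stable. Fn1 stood at the top of the mesenchymal list, and Snai1, a transcription factor of mesenchymal change, was 13.1-fold lower.

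MHC class I and interferon response genes were higher in the C3-TAg receptor-negative clusters. Of 18 MHC class I genes, 10 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.75 (0.08 to 1.39), above 99.8% of random lists. With TMM scaling the median was 0.31, with 8 higher and 3 lower. H2-Q7 and H2-Q6 were 12-fold and 7.31-fold higher, but these are near-identical copies whose counts are uncertain. B2m and H2-K1, chosen after their values were seen, were at 461.4 and 1062 CPM in WT and at 1210 and 2589 CPM in C3-TAg. Calr and Pdia3, chaperones of the loading complex, had log2 ratios of -0.29 and -0.33. Of 23 interferon response genes, 19 were higher and 0 lower, with a median of 1.34 (0.92 to 2.07), above 99.98% of random lists, and 14 higher and 1 lower with TMM scaling (median 0.89). Cxcl10, a T cell chemoattractant, was at 2.25 CPM in WT and 60.4 CPM in C3-TAg, and Ifi27l2a was 23.3-fold higher. Of 7 MHC class II genes, 5 were higher, with a median of 1.45 (-0.28 to 1.64), and 5 higher and 2 lower with TMM scaling. That median lay within the range of random lists (-0.20 to 1.74). Cd74, the invariant chain, was at 7.95 and 24.8 CPM. Ptprc, the leukocyte antigen CD45, was at 0.063 CPM in the C3-TAg receptor-negative cells.

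Of 17 measured immune checkpoint ligands, 7 were higher, 2 lower and 8 within 1.5-fold, with a median of 0.45 (-0.04 to 1.16), which is close to the TMM shift, and 6 higher and 5 lower with TMM scaling. Pvr, the ligand of TIGIT, was at 37.8 and 86.9 CPM, and Cd200 was 4.13-fold lower. Of 16 NF-kB and cytokine genes, 6 were higher and 4 lower, with a median of 0.46, and 4 higher and 6 lower with TMM scaling. Ccl2 and Ccl20, chemokines for monocytes and lymphocytes, were 23.8-fold and 13.8-fold higher, and complement C3 and Saa1 were 5.16-fold and 3.57-fold lower.

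Further lists were measured in the receptor-negative clusters. Hormone sensing genes had a median of -0.51 with 1 of 11 higher and 5 lower, Areg at 31.5 and 113.3 CPM and Igfbp5 at 1786 and 346.4 CPM. NRF2 targets had -0.35 with 1 of 12 higher and 4 lower, Nqo1 being 4.68-fold lower. With TMM scaling 8 hormone sensing genes and 8 NRF2 targets were lower, with medians of -0.96 and -0.79. Hypoxia and glycolysis genes had -0.15 with 4 of 16 higher and 7 lower, and Vegfa and the glucose transporter Slc2a1 were 5.70-fold and 5.26-fold lower. Wnt pathway genes had 0.98 with 6 of 10 higher and 1 lower, the inhibitor Sfrp2 being 75.4-fold lower. The Wnt median lay within the range of random lists (-0.01 to 1.33), and with TMM scaling it was 0.54 with 4 higher and 1 lower. Notch pathway genes had 0.31, cartilage matrix genes known as SOX9 targets 0.35 (mean -0.09), and squamous genes 0.25, and each of these 3 medians fell below 0 with TMM scaling. Over all alternatives the squamous median ran from -0.20 to 1.28. Dissociation and immediate early genes had 0.32, or -0.12 with TMM scaling, and Atf3 and Nr4a1 were 8.92-fold and 9.15-fold higher. Hspa1a was 1.5-fold lower, but its log2 ratio was 0.52 once cells with G2M UMIs were left out. Mitochondrially encoded genes had -0.14, none beyond 1.5-fold, but -0.59 with 7 of 13 lower after TMM scaling.

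The receptor-expressing clusters, 6 and 7 in WT against 5 in C3-TAg, differed less. Creb5, a transcription factor of the CRE-binding family, was 24.5-fold higher in C3-TAg, at 115.5 CPM against 4.71 CPM. Tnip3, Tesc, S100a14, Cxcl1, Lgals7, Tubb2b, Hilpda, Pdk4 and Fam107b were also among the highest, with log2 ratios between 1.66 and 3.74. Slpi, a secreted inhibitor of leukocyte proteases, was at 663.5 CPM in WT and 3963 CPM in C3-TAg. Defb1, an antimicrobial defensin, was 21.8-fold lower, at 2.46 against 53.7 CPM, and Cdh13, a cadherin without a transmembrane domain, 15.8-fold lower. Ak1, Spp1, Hivep3, Trbc2, Trf, Fam25c, Pir, Cxcl17, Dcn and Smad7 were the other lowest genes, with log2 ratios between -3.51 and -1.99. Dcn, also a fibroblast gene, was at 718.0 and 175.8 CPM in these cells, while Col1a1 was at 0.493 and 0.149 CPM.

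Interferon response genes were also higher in the C3-TAg receptor-expressing clusters, with 16 of 21 members at least 1.5-fold higher and a median log2 ratio of 1.37 (0.83 to 1.81), above all random lists. Usp18 and Rtp4 were 4.66-fold and 3.02-fold higher, and Irf1 and Bst2 were at log2 ratios of -0.34 and -0.28. The MHC class I list had a median of -0.39 (-0.54 to 0.03) with 1 of 18 members higher and 4 lower, or 8 lower with TMM scaling (median -0.48), and class II genes had -0.55 over 4 members. Tap2, a peptide transporter, was 2.19-fold lower. The receptor genes' own list, hormone sensing, had 1 of 13 members higher and 7 lower, with a median of -0.62 (-1.34 to 0.13). Stc2 and Calca were 2.65-fold and 2.54-fold lower, and Areg, an epidermal growth factor receptor ligand, was at 3206 and 4268 CPM. Milk genes had a median of -1.24 (-1.91 to -0.52), with Csn2 at 180.3 and 78.6 CPM. The G2M list had a median of 2.27 (1.51 to 3.39) over 16 members and the E2F and S phase list 0.53 (0.39 to 0.96). Mki67 was at 0.493 CPM in WT and 3.96 CPM in C3-TAg, against 173.8 CPM in C3-TAg receptor-negative cells. Milk genes in C3-TAg receptor-expressing cells stood at a median of 1.44% of their receptor-negative level. Free RNA from receptor-negative cells is thus not excluded for the G2M rise, and it was not tested. Squamous genes had 0.64 (0.07 to 1.65), with the keratin Krt16 at 3.80-fold and Sprr1a at 3.14-fold higher and Sfn 2.10-fold lower. Vtcn1 and Ido1 were the lowest of 14 immune checkpoint ligands, whose median was 0.00, and Ido1, which degrades tryptophan, was 3.14-fold lower. The remaining lists had medians between -0.30, for the Notch pathway, and 0.69, for cartilage matrix genes. The secretory, Wnt and mitochondrially encoded lists, at 0.01, 0.09 and 0.00, fell below 0 with TMM scaling.

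**Figure D3:**
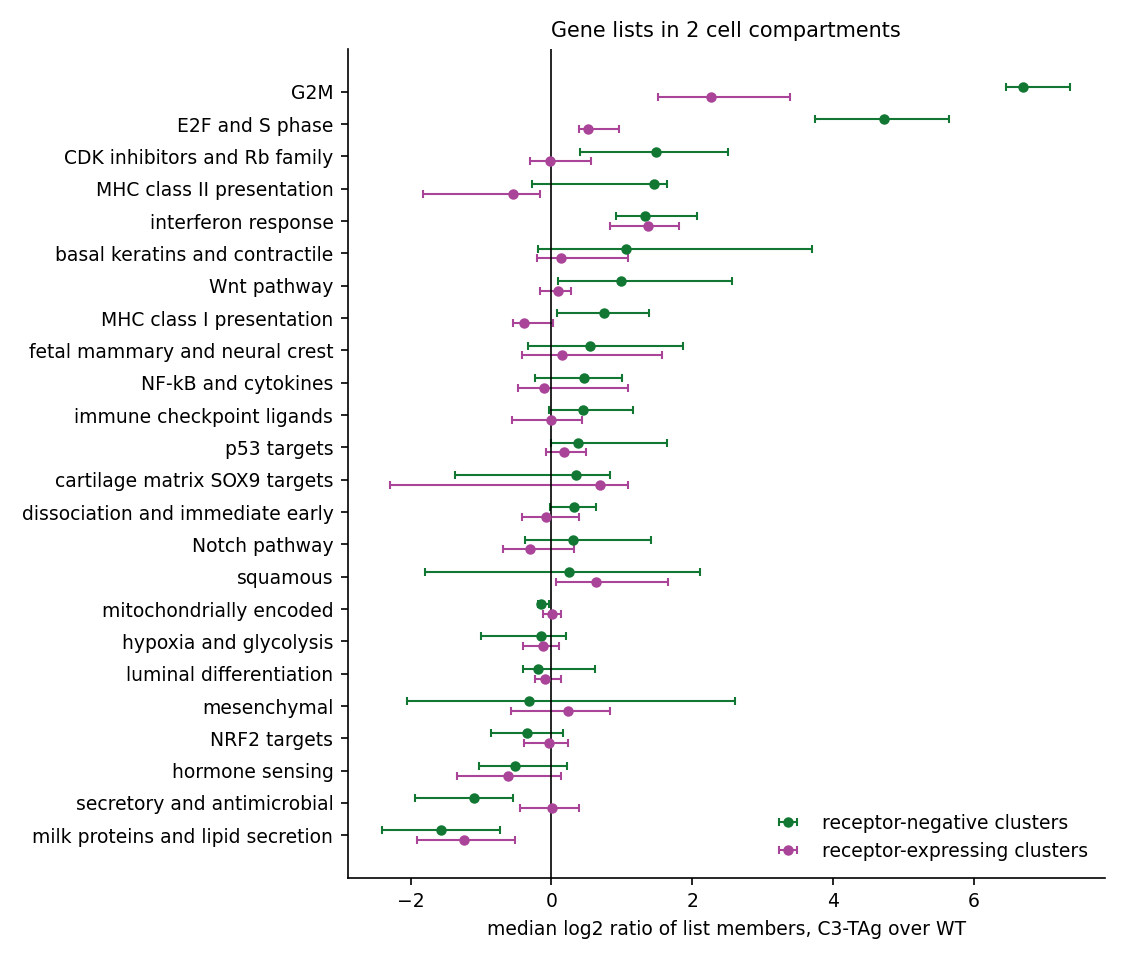
Median log2 ratio of C3-TAg over WT (x axis) for each gene list (y axis), in receptor-negative and receptor-expressing clusters. Whiskers are order-statistic intervals of the median over list members, which cover somewhat less than 95%. The interferon list stood at 1.34 and 1.37, while the MHC class I list stood at 0.75 in the receptor-negative and -0.39 in the receptor-expressing clusters.

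Clusters 1 and 2 held most C3-TAg receptor-negative cells and were each set against the WT receptor-negative cells. These clusters were formed on the same expression values, so the differences describe them and are not independent of the clustering. The milk list had a median log2 ratio of -0.80 (-1.52 to 0.10) in cluster 1 and -6.58 (-7.96 to -3.74) in cluster 2, where all 16 members were lower. The G2M list was higher in both, at 5.23 and 7.16. The interferon list stood at 0.78 in cluster 1 and 1.76 in cluster 2, and the MHC class I list at 0.41 and 0.98. The MHC class II list stood at -0.15 in cluster 1, with 0 of 6 higher and 2 lower, and at 2.34 in cluster 2. The NF-kB and cytokine list stood at -0.85 in cluster 1, with 3 of 16 higher and 11 lower, and at 1.01 in cluster 2, with 9 higher and 4 lower. TMM scaling moved the zero point by 0.30 in cluster 1 and 0.63 in cluster 2. The interferon medians were then 0.49 and 1.12 and the MHC class I medians 0.12 and 0.34, with 7 class I genes higher and 5 lower in cluster 2. The NF-kB and cytokine list then stood at -1.15 in cluster 1, with 3 higher and 12 lower, and at 0.38 in cluster 2, with 6 higher and 5 lower. Of the immune checkpoint ligands, 2 of 14 were higher and 4 lower in cluster 1, and 10 of 16 higher and 3 lower in cluster 2, with medians of 0.02 and 0.99. With TMM scaling the cluster 1 median was -0.28, and cluster 2 had 7 higher and 4 lower and a median of 0.36.

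Over all kept epithelial cells the genes with the highest ratios were again largely those of the cell cycle. Ccna2, Ankrd1, Cdkn2a, Pclaf, Cenpe, Mki67, Pbk, Fam111a, Diaph3, Clspn, Cdk1 and Birc5 had log2 ratios between 6.65 and 9.55, and Hey1, Cck, Clic6, Spp1, Tspan8, Arhgef6, Cbr2, Fcgbp, Ceacam10, Chil1, Lao1 and Fam25c between -5.68 and -3.00. Markers of other cell types were low in the receptor-negative clusters of both libraries. The endothelial list summed to 3.98 CPM in WT and 2.91 CPM in C3-TAg, the myeloid list to 9.50 and 7.19 CPM, the fibroblast list to 6.50 and 4.23 CPM, and the T or NK cell list to 0.310 and 0.692 CPM. The pericyte list summed to 20.4 and 24.9 CPM, the adipocyte list to 1.16 and 0.976 CPM, the erythroid list to 0.349 and 0.409 CPM and the Schwann cell list to 75.3 and 53.8 CPM, nearly all from Mbp. The B cell list reached 65.5 and 452.3 CPM, nearly all from Ly6d, which luminal cells also express. Xist, the X-inactivation transcript, was at 795.3 and 849.5 CPM, and no Y-linked gene of the list reached 20 UMIs.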

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

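The tests on MHC class I genes, on free RNA and on the scaling and depth of Vtcn1 were chosen after the result was seen, although the scalings and the thinning that the Vtcn1 tests used were planned, as was the test on the share of Csn2 UMIs in the cells with most of them. The rules by which the results in this part were picked were also set after the values were seen. Each genotype had 1 library, so none of these differences between compartments was tested across samples.

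The MHC class I list had a median log2 ratio of 0.75 in the receptor-negative and -0.39 in the receptor-expressing clusters, opposite directions under the same contrast. This difference was not tested across samples. Scaling may be asked about first: after TMM scaling in each compartment, the median difference over 18 members was 0.838 (0.012 to 1.453), with 13 members in that direction, which argues against scaling as the whole cause by a narrow margin. Immune cells among the receptor-negative cells would need 18.2 CPM of Ptprc to bring the extra H2-K1, and 0.063 CPM was seen, which argues against them. Scaling was left undecided, and the genotype, a difference in hormonal state and a difference between the libraries all stay open, untested.

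Milk genes had a median log2 ratio of -1.24 in the receptor-expressing clusters. Free RNA from milk-producing cells may have brought these UMIs, and the test left that open, because Plin2 lay 2.229 log2 units from the median carry-over of 7 milk genes, at 2.78% of its receptor-negative level in WT and 6.74% in C3-TAg. Over the 6 members that were lower, a set chosen after that result, the largest distance was 0.666, which decides nothing because the gene that broke the pattern was left out. Barcodes that also hold a milk-producing cell were not excluded either, since the 1% of WT cells with most Csn2 UMIs held 13.91% of them, between the bounds of 10% and 50% set beforehand, and 75.8% of cells held at least 1. Both explanations, and the genotype, stay open.

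Vtcn1 was at 35.3 CPM in WT and 7.91 CPM in C3-TAg receptor-expressing clusters, a log2 ratio of -2.16. The scaling that moved it nearest to 0 left it at -2.151, which argues against scaling as the cause. In cells thinned to 2000 UMIs the shares were 7.32% and 1.232%, with intervals that did not overlap, which argues against depth. The carry-over of milk genes would bring 0.153 CPM to the WT cells, but this test could not have come out otherwise. Vtcn1 was at only 16.9, 15.6 and 12.8 CPM in the WT receptor-negative clusters 3, 4 and 10, under the level seen. These levels argue against free RNA from those clusters as the source. The genotype and a difference between the libraries stay open, untested, and likely causes cannot be ranked from 1 library per group. The size of the ratio also depends on the mix of WT clusters 6 and 7, which had 27.7 and 44.4 CPM of Vtcn1.

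Of the genes picked by ratio or from the gene lists in the receptor-negative and receptor-expressing comparisons, 6 had ratios of at least 1.5-fold in opposite directions under both scalings. These were Glycam1 (2.292 and -2.879), H2-Q7 (3.589 and -1.057), Hilpda (-1.569 and 1.689), Igfbp5 (-2.366 and 0.717), Pdk4 (-1.393 and 1.68) and Slpi (-0.765 and 2.579), as log2 ratios. Aqp3 (-1.49 and 1.32) and Ly6d (2.79 and -0.94), named in the report for other reasons, also had opposite directions. These differences were not tested. Glycam1 was also a leading gene of cluster 12, and in WT it was at 46.3 CPM in receptor-negative and 30.2 CPM in receptor-expressing cells. Free RNA from other cells is not excluded for it. H2-Q7 and H2-Q6 are near-identical copies, so the H2-Q7 values are uncertain.

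Sox9 was also seen in the clusters outside the comparisons, above the level that a count of 0 allows except in the 4 C3-TAg cells of cluster 13 (108.0 CPM from 3 UMIs, equal to the limit). It was at 388.382 CPM in the 19 WT cells and 546.055 CPM in the 11 C3-TAg cells of cluster 12, against limits of 13.1 and 27.3 CPM, and at 164.681 CPM in the 25 WT cells of cluster 13, against 19.0 CPM. These limits are low and no background level was set beside them. Epcam, an epithelial gene, was at 2326, 491.5 and 1837 CPM in the same cells, and the WT cells of cluster 12 held 4748 CPM of Csn2 and 2348 CPM of Krt8, so the Sox9 UMIs are not shown to come from endothelial or myeloid cells. The WT cells of cluster 12 also held 1820 CPM of Krt14 and 183.3 CPM of Krt5, which are basal genes. No biological explanation was tested.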

How the results depend on the processing

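The alternatives were chosen before the data were examined, except leaving out epithelial clusters of under 100 cells, which was chosen after seeing the data. Of 1012 values of 88 results under alternatives, 89 moved beyond the interval of the main value, 48 of them from the depth of thinning and 41 from other settings. For list medians this was the often wide interval over members, and for the other results the counting interval. The receptor-negative MHC class I median thus went from 0.75 to 0.305 with TMM scaling without counting as moved. Of 750 log2 values, 709 kept their sign. The others were list medians, most of them near 0, and ratios of Vtcn1 in cells with over without a Sox9 UMI, such as WT receptor-expressing cells at 5000 UMIs (-0.318, an interval that excluded 0). Of 3470 values of 410 named-gene ratios, 929 moved and 4 reversed. Where no cause is named, the cause was not tested.

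The 4 reversed values were Wfdc2 in the receptor-negative clusters with called doublets kept (-0.119), Hspa1a there with cells holding G2M UMIs left out (0.515), and Col9a3 in cluster 2 with TMM scaling (-0.004) and with those cells left out (-0.026).

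TMM scaling gave Sox9 log2 ratios of -0.561 over all epithelial cells, -0.578 in receptor-negative and -0.556 in receptor-expressing clusters, and Vtcn1 ratios of -1.119 over all epithelial and -0.652 in receptor-negative cells. In receptor-negative clusters it moved the list medians of interferon response to 0.89, G2M to 6.255, p53 targets to -0.07, luminal differentiation to -0.631, dissociation and immediate early genes to -0.121 and mitochondrially encoded genes to -0.588. Leaving milk and mitochondrially encoded genes out of the total gave Sox9 ratios of -0.328 over all epithelial and -0.254 in receptor-negative cells, and -0.264 for mitochondrially encoded genes. The shift of the zero point by the scaling itself makes these moves.

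Leaving out cells with 2 or more G2M UMIs gave Sox9 ratios of -0.276 over all epithelial and -0.185 in receptor-negative cells, and Vtcn1 ratios of -1.02 and -0.025. This step falls mostly on C3-TAg, where 79.086% of receptor-negative cells held that many without thinning, against 2.198% in WT. It moved the receptor-negative medians of interferon response to 0.818, E2F and S phase to 3.608 and G2M to 2.612, and the receptor-expressing G2M median to 1.409. Clustering each library on its own moved dissociation and immediate early genes to -0.029, the stromal or immune share to 0.979% in WT and 4.651% in C3-TAg, and the C3-TAg receptor-negative share to 73.672%. A mitochondrial maximum of 20% moved mitochondrially encoded genes to -0.205 and the WT receptor-expressing share with Vtcn1 to 6.022%.

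With called doublets kept, receptor-expressing clusters held 36.322% of WT and 20.147% of C3-TAg cells and receptor-negative ones 63.07% and 79.641%. The share of C3-TAg receptor-expressing cells with Sox9 was then 45.797%, and receptor genes with Elf5 or Kit were found in 7.144% of WT and 4.516% of C3-TAg receptor-negative cells. With at least 1000 genes per cell, the C3-TAg share with Krt5, Krt14 or Krt17 was 3.991% in receptor-expressing cells, and with a receptor gene and Elf5 or Kit 3.144% in receptor-negative and 0.293% in receptor-expressing cells. With at least 3 G2M UMIs, the cycling share was 38.053% in C3-TAg receptor-negative cells, and 0.037% in WT and 0.587% in C3-TAg receptor-expressing cells.

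Shares of cells with a UMI depend on depth by construction. The values that follow are for WT and then C3-TAg, thinned to 5000 UMIs and, in parentheses, not thinned. In receptor-negative cells they were 77.144% and 74.481% (89.523% and 86.29%) for Sox9, 7.334% and 7.269% (16.908% and 12.409%) for Vtcn1, 0.609% and 71.788% (2.198% and 79.086%) for 2 or more G2M UMIs, 8.114% and 66.614% (14.172% and 74.923%) for Krt5, Krt14 or Krt17, 3.46% and 6.829% (6.174% and 9.27%) for Acta2, Myh11 or Tagln, and 20.931% and 14.608% (44.902% and 30.298%) for a receptor gene with Elf5 or Kit. In receptor-expressing cells they were 78.46% and 65.447% (86.17% and 73.681%), 15.093% and 3.66% (25.899% and 5.627%), 0.569% and 3.474% (1.834% and 6.448%), 1.479% and 7.568% (2.458% and 10.785%), 1.631% and 1.179% (2.971% and 1.817%), and 2.01% and 1.675% (3.595% and 1.934%), in the same order.

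Among these results, the lower Vtcn1 in C3-TAg receptor-expressing clusters kept its direction under every alternative run. Depth limits Vtcn1, since 21 C3-TAg receptor-expressing cells held a UMI of it after thinning to 2000 UMIs.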

Other observations

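The test of Cdkn2a in this part was chosen after the result was seen, and so were the genes named here.

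A hypothesis was that more cycling cells may explain the higher Cdkn2a in the C3-TAg receptor-negative clusters. Clusters 2 and 8 had similar Mki67, at 247.1 and 286.7 CPM, but Cdkn2a was at 133.5 CPM (128.9 to 138.3) in cluster 2 and 0.975 CPM (0.392 to 2.008, 7 UMIs) in cluster 8. This argues against cycling alone as the cause. Which cells carried Cdkn2a was part of how the clusters formed, so the value describes these clusters.

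Cluster 11 held 55 C3-TAg cells and no WT cell. It had 1587 CPM of Cdkn2a, 991.8 CPM of Fn1, 501.0 CPM of the intermediate filament gene Vim, 212.6 CPM of Sox11 and 680.1 CPM of the luminal keratin Krt8, against 3149 CPM of Krt8 in cluster 1.

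Of 2313 genes with at least 50 CPM in both compartments, 10 were at least 2-fold higher in C3-TAg in both, 22 were at least 2-fold lower in both and 4 went 2-fold in opposite directions. Creb5 had log2 ratios of 2.91 in the receptor-negative and 4.62 in the receptor-expressing clusters, S100a14 of 2.75 and 2.80, and Myc, a transcription factor of growth, of 1.13 and 1.10. Spp1 had -4.01 and -3.42, Vegfa -2.51 and -1.21, and Ccnd1 -1.21 and -1.64. The genes lower in both include Spp1, Csn2, Csn3, Csn1s1, Csn1s2a, Trf, Mfge8 and Lcn2, whose levels in receptor-expressing cells were a small part of those in receptor-negative cells (Spp1 at 323.3 against 23766 CPM in WT), so free RNA is not excluded for them.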
